A study of Mus musculus with 12 samples.

How the data were processed

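The deposited table holds 22393 spots of an Agilent mouse oligonucleotide array for 12 samples, 4 each of pioglitazone, telmisartan and irbesartan, and all 12 were used. Each array carried drug and vehicle RNA in 2 channels, and per the labels the RNA of each side was pooled from several cultures. The labels give the channel of the drug, which was channel 1 on arrays 1 and 3 and channel 2 on arrays 2 and 4 of each drug. They do not say whether the 4 arrays of a drug used 1 pool of RNA or several, nor whether the drugs shared 1 vehicle RNA. The array was therefore the unit of every test.

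The deposited values were read as log10 ratios of an array's channels. This unit was inferred from the values, since no header states it: they are symmetric around 0 and end at -2 and 2, as log10 ratios of Agilent's extraction software do, and 273 values lie at that limit, 272 of them in control-like spots. Every array median lies within 0.00264 of 0, so the arrays appear to have been normalised before deposition, and they were kept as deposited. Background correction, dye normalisation and the reason for empty cells are not stated. The table holds no intensities, background values or saturation marks, so signal over background is unknown, and the share of empty spots per array (7.47% to 20.17%) is the sole measure of depth.

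Values were multiplied to the log2 scale and turned to drug over vehicle. Opposite channel orders of a drug anticorrelated, with a mean correlation of -0.4815 over spots with a gene, which showed that the ratios had not been turned before. Over all spots the mean correlation was 0.7514, because 471 control-like spots had an absolute log10 ratio above 0.3 with the same sign in both orders. None of the 471 (0 spots) has a gene, and they were left out, a choice made after the values were seen. Since they were chosen by their sign, the correlation of -0.4527 without them is lower by construction. Which channel is the numerator is not stated. Channel 2 over channel 1 was taken as likely, because on pioglitazone arrays it puts 17 of 25 PPAR-gamma targets, and 9 of the 12 that differ at least 1.5-fold, above 0, and 6 of 8 thiazolidinedione-repressed genes below 0. The direction of these lists under pioglitazone is therefore not an independent result.

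Genes were taken from the platform annotation: 18218 spots had 1 gene symbol, 16 had several and 4159 had none. Of the 18218, 18175 were matched to the gene table by Entrez ID and 43 were not. Repeat spots (48 sets of 10 or 11 spots) were averaged; the median SD between repeats on an array was 0.07 on the log2 scale. Features with values on at least 3 of the 4 arrays of each drug were tested, which kept 17217 of 21486. Annotation positions on the genome were not used.

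Differential expression was tested with limma 3.58.1 in R 4.3.3. One fit of the 12 arrays held a coefficient for each drug and a dye coefficient shared by all arrays, and limma's moderated test was applied to each drug and to each difference between drugs. Adjusted p-values are Benjamini-Hochberg values over the 17217 features within each comparison, with a threshold of 0.05, and all tests are two-sided. Intervals are 95% intervals from the same fit. The fit assumes that the drugs share 1 spread per feature. Gene lists, 31 in number with at least 5 measured genes each, were fixed before the data were examined, as were the comparisons and the first group of alternatives given below. Their shift against all other genes was tested with camera at its preset correlation of 0.01 on 13152 genes, adjusted over the 31 lists within a comparison. Each was tested again with the correlation estimated from the data, and with fry, which asks whether a list's genes move on balance 1 way and compares them with no other genes. Of the lists past the camera test, 8 of 13 held with the estimated correlation for pioglitazone, 7 of 15 for telmisartan, 13 of 16 for irbesartan, 9 of 13 for pioglitazone against telmisartan, 5 of 10 for pioglitazone against irbesartan and 7 of 16 for telmisartan against irbesartan. List members and counts use genes, with several spots of a gene averaged.

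Named genes followed a rule fixed in advance as well. It takes, for each drug, the 10 largest rises and the 10 largest falls past the threshold with 1 sign on all measured arrays, up to 4 members past the threshold of each list, and 12 genes named in advance (Pparg, Fabp4, Adipoq, Cd36, Pdk4, Angptl4, Lpl, Slc2a4, Agt, Agtr1a, Retn and Lep). For each difference between drugs it takes the 5 largest in each direction. A gene with several spots is named by the spot with the smallest p. Members of lists and genes named in advance were added for the differences between drugs after their values were seen, by the same rule. Of the genes the rule selects, the report names the larger changes.

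Some abundant genes shared 1 ratio. Spots within 0.0015 (log10) of the Fabp4 ratio on the arrays of pioglitazone and irbesartan with the drug in channel 1 were counted, and 5 spots shared it on at least 3 of these 4 arrays. Chance would give 0.00033 if the arrays were independent. Arrays of 1 drug and channel order correlate, so that figure is too low. Fewer of these spots shared a ratio on telmisartan arrays 1 and 3, and on irbesartan arrays 2 and 4 some shared the ratio of Lars2. Their values were kept and are marked where they are given.

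Arrays with the same number in different drugs deviated alike from their drug means (correlations of 0.237 to 0.514). About the mean of the same channel order these correlations were -0.032 to 0, so the numbers shared the channel order and nothing more, and no pairing was used. With the number as a block, 8186, 6642 and 4929 features passed for pioglitazone, telmisartan and irbesartan, and 2047, 2495 and 1082 for pioglitazone against telmisartan, pioglitazone against irbesartan and telmisartan against irbesartan.

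The procedure was tested on simulated data of the same size with 50 changed features per fold. Of these, 68%, 94%, 98% and 100% were called at 1.2-fold, 1.5-fold, 2-fold and 3-fold for a drug against vehicle, and 32%, 84%, 94% and 100% for a difference between drugs. False calls were 14 (7.22% of calls) and 10 (6.06% of calls). A simulated list of 20 genes shifted by 0.15 was called (adjusted p = 7.29e-16), and 0 of 31 unshifted lists were. In the simulation genes varied independently of each other, so it does not show how often lists of correlated genes are called falsely.

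Alternatives chosen in advance were no dye term, the array number as a block, dye-swap pairs averaged, centred arrays, scaled arrays, complete features, no filter, robust variance estimation, spots of a gene averaged, a separate fit for each comparison, array weights, and leaving out each array. Other splits of the samples were counted by turning arrays of a drug (8 patterns) or by regrouping the 8 arrays of 2 drugs (35 splits). Alternatives added after the data were seen were control-like spots kept, repeat spots not averaged, a dye term per drug, spots that share a ratio left out, a minimum of 1.5-fold, arrays scaled for the list tests, and all spots for the check of direction. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.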

Results

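Cultured mouse cells were treated with pioglitazone, telmisartan or irbesartan, and their RNA was compared with RNA from vehicle-treated cells on 12 Agilent mouse oligonucleotide arrays, 4 for each drug. Pioglitazone is a thiazolidinedione that activates the nuclear receptor PPAR-gamma, the regulator of fat cell genes. Telmisartan and irbesartan block the angiotensin type 1 receptor, and the series title describes such blockers as PPAR-gamma activators. The arrays therefore ask which genes each blocker changes, which of these pioglitazone also changes, and where the related blockers differ. Each array held drug and vehicle RNA together, with the drug in channel 1 on arrays 1 and 3 and in channel 2 on arrays 2 and 4. The labels state neither the cell type nor the dose nor the time of treatment. Between 17877 and 20721 of the 22393 spots on an array had a value, which left from 7.47% of spots empty on irbesartan array 2 to 20.17% on telmisartan array 3. After filtering, 17217 features (spots, or averages of repeat spots) were tested, which covered 13950 genes. Values below are fitted log2 ratios of drug over vehicle ± SE, from 4 arrays of a drug, or 3 where stated, and the number of arrays limits their precision. The SE comes from the fit of all 12 arrays, in which the drugs share 1 spread per feature. It does not show how closely the arrays of a single drug agreed. Every p-value rests on the spread between arrays, which may be technical, because the labels do not say whether the 4 arrays of a drug shared 1 pool of RNA. Which channel stands above the ratio is not stated either: the reading used here is the likely one, and under the other reading every "higher" would be "lower".

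Pioglitazone raised the scavenger receptor gene Olr1 (3.45 ± 0.12, adjusted p = 1.66e-09), the fatty acid elongase gene Elovl3 (2.64 ± 0.05) and Pdk4, whose kinase switches off pyruvate dehydrogenase (2.05 ± 0.04). It lowered the antimicrobial peptide gene Camp (-3.16 ± 0.12, adjusted p = 3.4e-09), the sulfotransferase gene Sult1a1 (-2.09 ± 0.03) and matrix protein genes such as Ogn (-2.05 ± 0.03). Genes of mitochondrial respiration, fatty acid oxidation, cholesterol synthesis and the cell cycle were higher as groups, and genes of the extracellular matrix and fibroblast markers were lower. In all, 8587 of 17217 features passed the threshold, 4064 higher and 4523 lower, and 981 of them differed at least 1.5-fold. At an unadjusted p under 0.05 there were 9528.

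The other genes among the 10 with the largest rise under pioglitazone were Krt23 (2.58), Arxes1 (2.05), 4931406C07Rik (1.72), the carbonyl reductase gene Cbr3 (1.69), Cycs for cytochrome c (1.68, and 1.49 at its other spot), Bhlhb9 (1.60) and Nus1 (1.56). Among the 10 with the largest fall were Phkg1 (-2.24), the neuropeptide receptor gene Adcyap1r1 (-2.14), the cytochrome P450 gene Cyp2f2 (-1.95) and the matrix protein genes Abi3bp (-1.89), Comp (-1.87) and Tgfbi (-1.82). Each had 1 sign on its 4 arrays. Defb7 (-1.97 ± 0.59, n = 3, adjusted p = 0.0223) also fell, but without pioglitazone array 1 its value was -0.35 (adjusted p = 0.135), and with the array number as a block it was -1.82 (adjusted p = 0.0833).

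Of 69 measured oxidative phosphorylation genes, which build the respiratory chain, 63 rose with pioglitazone, 2 fell and 4 did not pass (median 0.35, camera adjusted p = 3.53e-18). With p-values adjusted over the list alone, 63 rose and 3 fell. Cox7b (0.79), Ndufa5 (0.73) and Ndufa4 (0.69) followed Cycs. In the citrate cycle list 16 of 22 genes rose, among them Idh3a (1.19), Cs for citrate synthase (0.83) and Dld (0.82), and 2 fell (median 0.35, camera adjusted p = 7.08e-06). Over the list alone, 18 rose and 2 fell. Fatty acid oxidation genes rose in 19 of 24 cases and fell in 0 (median 0.38, camera adjusted p = 6.02e-09), with 20 and 0 adjusted over the list alone. Hadhb of the mitochondrial trifunctional protein rose by 1.05, the carnitine carrier gene Slc25a20 by 0.89 and the dehydrogenase gene Acadl by 0.70. Cholesterol synthesis genes rose in 16 of 20 cases and fell in 1 (median 0.53, camera adjusted p = 5.35e-08), with 17 and 1 adjusted over the list alone. Hmgcs1 (1.02), the sterol sensor gene Insig1 (0.95) and the isomerase gene Idi1 (0.93) were among the largest within the list. In the brown fat list 7 of 11 genes rose and 2 fell, adjusted over the list alone too (median 0.19, camera adjusted p = 0.0138, adjusted p = 0.0622 with an estimated correlation). The hormone gene Fgf21 was at 0.45, beside Elovl3 and Pdk4.

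Extracellular matrix genes fell in 35 of 43 cases and rose in 1 (median -0.46, camera adjusted p = 1.1e-13), with 35 and 2 adjusted over the list alone. The proteoglycan genes Dcn (-1.82) and Lum (-1.74), fibronectin's gene Fn1 (-1.67) and the collagen cross-linking enzyme gene Lox (-1.48) fell most within this list. Fibroblast and preadipocyte markers fell in 11 of 15 cases and rose in 2, adjusted over the list alone too (median -0.67, camera adjusted p = 3.09e-06). Pdgfra (-1.41), Gas6 (-1.36) and Dlk1, an inhibitor of fat cell formation (-1.03), were among them. Of 23 actin and contractile genes 17 fell and 3 rose, adjusted over the list alone too, with Myl9 at -1.27 and Cnn2 at -1.23 (median -0.37, camera adjusted p = 6.71e-05, adjusted p = 0.0767 with an estimated correlation). Inflammation genes fell in 15 of 28 cases and rose in 3, adjusted over the list alone too (median -0.11, camera adjusted p = 0.00277, adjusted p = 0.127 with an estimated correlation). The acute-phase protein genes Orm2 (-1.44), Orm1 (-1.37) and Hp (-1.20) and the pentraxin gene Ptx3 (-1.05) fell most within the list. Ribosomal protein genes fell in 35 of 63 cases and rose in 5, adjusted over the list alone too, with Rpl3 at -0.52 (median -0.13, camera adjusted p = 0.000129, adjusted p = 0.177 with an estimated correlation).

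Cell cycle genes rose in 26 of 34 cases and fell in 4 (median 0.30, camera adjusted p = 7.08e-06), with 26 and 5 adjusted over the list alone. The centromere genes Cenpa (1.24) and Cenpe (1.07), Cks2 (0.93) and the nucleotide reductase gene Rrm2 (0.75) rose most within the list. Genes of the ER stress response rose in 17 of 24 cases and fell in 6, adjusted over the list alone too, with the asparagine synthetase gene Asns at 0.96 and Dnajb9 at 0.79 (median 0.24, camera adjusted p = 0.000661, adjusted p = 0.0573 with an estimated correlation).

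PPAR-gamma target genes served to set the direction of the ratios, so their direction under pioglitazone is no result. With that reading 15 of 25 were higher and 7 lower (15 and 8 adjusted over the list alone; median 0.19, camera adjusted p = 0.00196), among them Olr1, Pdk4, Fabp5 (1.47), Hilpda (1.33), the fatty acid transporter gene Cd36 (1.00 ± 0.03) and the lipase inhibitor gene Angptl4 (0.98 ± 0.03). Pparg itself fell by 1.09 ± 0.03 (adjusted p = 1.39e-10). Genes known to be repressed by thiazolidinediones in fat also entered the choice of reading, so their fall is not an independent result. Of the 8 measured on the pioglitazone arrays 6 passed the filter for empty spots. Of these 6, 4 fell and 1 rose, with 4 and 2 adjusted over the list alone (median -0.43, camera adjusted p = 0.0545). The cortisone reductase gene Hsd11b1 fell by 1.00. The resistin gene Retn (-0.62 ± 0.02) and the angiotensinogen gene Agt (-0.60 ± 0.02) were also among the falls. The list's camera test passed without pioglitazone arrays 1 (0.0494), 3 (0.045) or 4 (0.0307) or telmisartan array 3 (0.0485), with scaled arrays (0.0462) and with no dye term (0.0342). Agtr1a, the receptor the blockers bind, was at 0.07 ± 0.05 (adjusted p = 0.233), the glucose transporter gene Slc2a4 fell by 0.11 ± 0.03, and the leptin gene Lep was at 0.11 ± 0.02 (adjusted p = 0.00191, or 0.109 with no dye term).

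Fabp4, Lpl, Adipoq, Aldoa and Cidec, which code for abundant fat cell and glycolytic proteins, shared 1 identical ratio with several other spots on some arrays, for a reason that is not known, so their values may not measure the genes there. Fabp4 read -0.88 and -1.04 on pioglitazone arrays 1 and 3 and 0.39 and 0.16 on arrays 2 and 4. Its fitted value was -0.34 ± 0.14 (adjusted p = 0.0597), and it passed without pioglitazone array 2 (0.0251) or telmisartan array 4 (0.00814). It also passed with scaled arrays (0.0211), its own fit (0.00426), array weights (0.0241) and a dye term per drug (0.0314). Lpl had a fitted value of -1.12 ± 0.14 (adjusted p = 3.73e-05) and Adipoq, for adiponectin, one of -0.95 ± 0.08 (adjusted p = 1.38e-06).

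No group shift passed the test under pioglitazone in the lists of lipogenesis (9 higher and 8 lower of 20, camera adjusted p = 0.711), lipolysis (5 and 1 of 9, 0.164), glucose uptake and glycolysis (8 and 5 of 18, 0.204), insulin signalling (2 and 9 of 19, 0.111), secreted factors (6 and 7 of 15, 0.21) or adipogenic regulators (7 and 15 of 28, 0.249). Nor did one pass for the renin-angiotensin system (2 and 5 of 14, 0.495), interferon response (4 and 12 of 24, 0.131), oxidative stress (13 and 9 of 29, 0.277), heat shock (6 and 2 of 14, 0.159), the circadian clock (2 and 8 of 17, 0.0825, or 0.0382 with no dye term) or glucocorticoid response (5 and 6 of 15, 0.8). All of these lists but lipogenesis passed by fry, which compares with no other genes. Among them were secreted factors (fry adjusted p = 9.36e-09) and interferon response (1.43e-08). Single members moved far: the lipogenic regulator gene Thrsp fell by 1.49, the lactate carrier gene Slc16a1 rose by 1.29, the guanylate binding protein gene Gbp3 fell by 1.02 and the glutathione transferase gene Gstm1 fell by 1.22. The macrophage, endothelial, muscle, hepatocyte and blood cell lists did not shift as groups in the camera test with any drug. Of the other cell type lists, fibroblast markers passed with each drug and brown fat genes with pioglitazone and irbesartan. The lists therefore do not show that the mix of cells was unchanged. Under pioglitazone the macrophage list had 0 genes higher and 1 lower of 12 (camera adjusted p = 0.852), the endothelial list 3 and 3 of 14 (0.923), the muscle list 5 and 4 of 18 (0.866), the hepatocyte list 1 and 1 of 18 (0.488) and the blood cell list 4 and 1 of 12 (0.923). For oxidative stress, endothelial, muscle and blood cell genes the median, the mean and the test did not all have 1 sign.

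**Figure D1:**
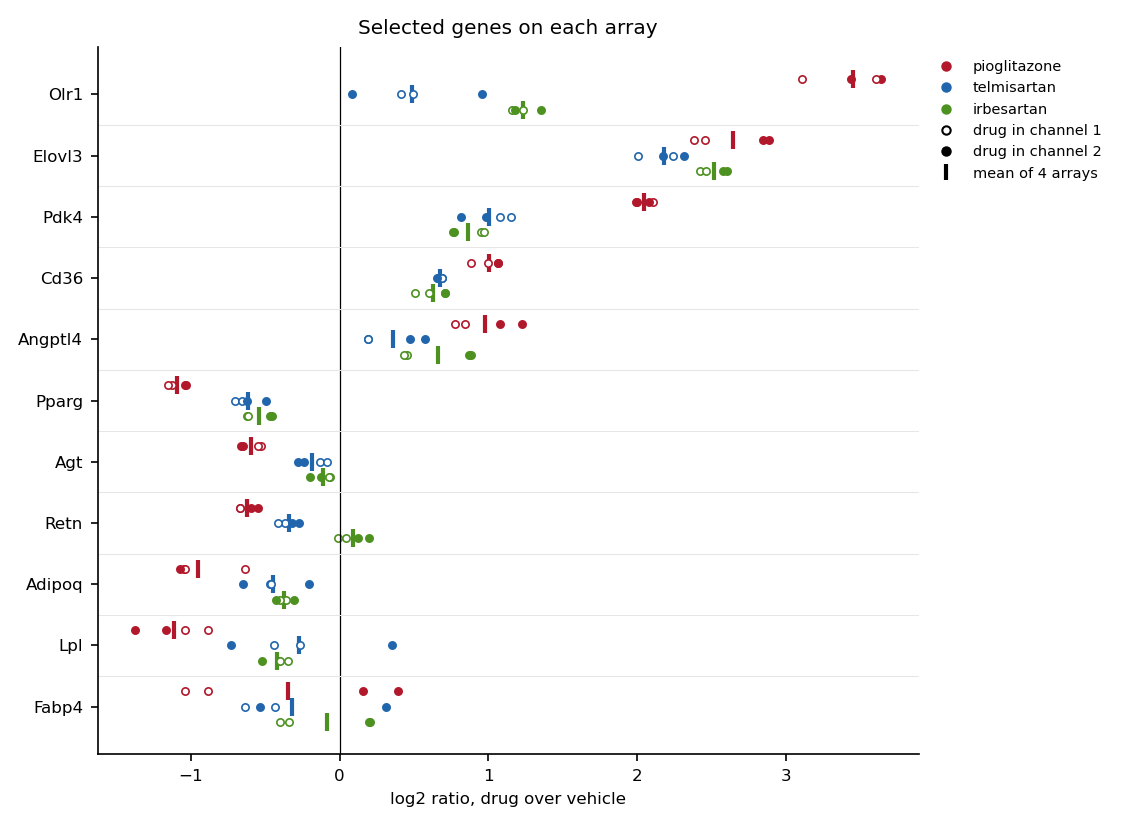
Log2 ratios of drug over vehicle on each array for 11 named genes, with the drug in channel 1 or channel 2 marked for each array. Olr1, Elovl3 and Pdk4 lie above 0 and Pparg and Agt below 0 on all 12 arrays, whereas Fabp4 changes sign with the channel order on the pioglitazone arrays.

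Telmisartan also raised Elovl3 (2.19 ± 0.05, adjusted p = 1e-09), Krt23 (1.54 ± 0.09) and the cholesterol pathway gene Idi1 (1.12 ± 0.02). It lowered Camp (-1.69 ± 0.12, adjusted p = 8.73e-07), Adcyap1r1 (-1.64 ± 0.16) and Sult1a1 (-1.43 ± 0.03). Genes of cholesterol synthesis, respiration and the ER stress response were higher, matrix genes and fibroblast markers were lower, and interferon response genes such as Isg15 were higher, a call that did not hold with an estimated correlation (adjusted p = 0.0871). Of 17217 features 7067 passed, 3432 higher and 3635 lower, with 414 at 1.5-fold or more and 8402 at an unadjusted p under 0.05. With no dye term 4757 passed. In a separate fit of the telmisartan arrays 4771 of 17519 features passed, fewer than the 6397 of 19344 in that of irbesartan. Which blocker changed more features therefore depended on the fit.

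Further large rises with telmisartan were Nus1 (1.29), Steap1 (1.29), Gpcpd1 (1.18), Stambpl1 (1.14), 4931406C07Rik (1.14), the ER oxidase gene Ero1a (1.12) and Tcea1 (1.12). Further large falls were Sncg (-1.38), Cyp2f2 (-1.36), the thrombomodulin gene Thbd (-1.32), Hp (-1.26), Dcn (-1.22), Sparcl1 (-1.21) and Rasl11a (-1.14). Cholesterol synthesis genes rose in 17 of 20 cases and fell in 0 (median 0.49, camera adjusted p = 1.77e-10), with 18 and 0 adjusted over the list alone. Insig1 (0.83) and Lss (0.78) followed Idi1. Oxidative phosphorylation genes rose in 55 of 69 cases and fell in 0 (median 0.23, camera adjusted p = 1.72e-14), with 56 and 0 adjusted over the list alone, led by Cycs (0.96, and 1.14 at its other spot) and Ndufa5 (0.50). Fatty acid oxidation genes rose in 12 of 24 cases and fell in 1 (median 0.10, camera adjusted p = 0.00207), with 12 and 2 adjusted over the list alone, and Slc25a20 was at 0.61. Citrate cycle genes rose in 12 of 22 cases and fell in 2, or 17 and 2 adjusted over the list alone, with Idh3a at 0.92 (median 0.16, camera adjusted p = 8.24e-05, adjusted p = 0.0685 with an estimated correlation). ER stress genes rose in 19 of 24 cases and fell in 3, adjusted over the list alone too (median 0.36, camera adjusted p = 3.13e-07). Asns (0.81), the chaperone gene Hspa5 (0.69) and the stress-induced transcription factor gene Ddit3 (0.58) were among them. Interferon response genes rose in 10 of 24 cases and fell in 1, or 11 and 1 adjusted over the list alone, led by Isg15 (0.92), Mx2 (0.70) and Ifit1 (0.69, n = 3). Their shift (median 0.15, camera adjusted p = 0.0413) gave an adjusted p = 0.0871 with an estimated correlation, 0.0543 with the array number as a block and 0.0512 with dye-swap pairs averaged. Cell cycle genes rose in 20 of 34 cases and fell in 4, or 22 and 6 adjusted over the list alone, with Cenpe at 1.01 (median 0.15, camera adjusted p = 0.00274, adjusted p = 0.103 with an estimated correlation).

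With telmisartan, matrix genes fell in 27 of 43 cases and rose in 2 (median -0.26, camera adjusted p = 3.68e-10), with 29 and 2 adjusted over the list alone. Lum (-0.85), Col1a2 (-0.84) and Col3a1 (-0.82) followed Dcn. Fibroblast markers fell in 12 of 15 cases and rose in 1, adjusted over the list alone too, with Vim at -0.81 and Pdgfra at -0.81 (median -0.34, camera adjusted p = 3.07e-07). Actin and contractile genes fell in 17 of 23 cases and rose in 2, or 17 and 3 adjusted over the list alone, with Myl9 at -1.13 (median -0.33, camera adjusted p = 3.32e-05, adjusted p = 0.0685 with an estimated correlation). Inflammation genes fell in 16 of 28 cases and rose in 3, adjusted over the list alone too, with Orm2 at -1.04 and the chemokine gene Ccl2 at -0.61 (median -0.21, camera adjusted p = 5.69e-05, adjusted p = 0.0641 with an estimated correlation). Of the 6 thiazolidinedione-repressed genes 4 fell and 0 rose, adjusted over the list alone too (median -0.26, camera adjusted p = 0.00381): Hsd11b1 (-0.67), Ccl2, Retn (-0.34 ± 0.02) and Agt (-0.18 ± 0.02). Insulin signalling genes fell in 9 of 19 cases and rose in 3, or 10 and 3 adjusted over the list alone, with the adaptor gene Grb14 at -0.61. That shift (median -0.17, camera adjusted p = 0.0408) had an adjusted p = 0.0871 with an estimated correlation, and 0.0937 without telmisartan array 2 or 0.0563 without array 3. Adipogenic regulators fell in 13 of 28 cases and rose in 5, or 15 and 6 adjusted over the list alone, with Srebf1 at -0.70 and Pparg at -0.62 ± 0.03 (median -0.12, camera adjusted p = 0.0205, adjusted p = 0.226 with an estimated correlation). Ribosomal protein genes fell in 23 of 63 cases and rose in 5, adjusted over the list alone too, with Rpl3 at -0.35 (median -0.07, camera adjusted p = 0.019, adjusted p = 0.442 with an estimated correlation).

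PPAR-gamma targets rose in 11 of 25 cases and fell in 4 with telmisartan, or 12 and 4 adjusted over the list alone. Pdk4 (1.01 ± 0.04), the glycerol channel gene Aqp7 (0.88), Cd36 (0.68 ± 0.03) and Angptl4 (0.36 ± 0.03) rose. The shift of the list (median 0.04, camera adjusted p = 0.0775) passed without the spots that shared a ratio (median 0.16, 0.00978) and without telmisartan arrays 3 (median 0.04, 0.0434) or 4 (median 0.095, 0.0452). Slc2a4 fell by 0.17 ± 0.03, and Lep was at -0.04 ± 0.02 (adjusted p = 0.24). Agtr1a was at 0.11 ± 0.05 (adjusted p = 0.0893, or 0.0224 without telmisartan array 3). Of the genes with shared ratios, Fabp4 and Lpl shared 1 on telmisartan array 1, and Fabp4 did on array 3. Adipoq was at -0.45 ± 0.08 (adjusted p = 0.000697) and Fabp4 at -0.32 ± 0.14 (0.0865, or 0.0448 with scaled arrays and 0.047 with a dye term per drug). Lpl was at -0.27 ± 0.14 (0.137, or 8.36e-05 without telmisartan array 2 and 0.00701 with array weights). The remaining lists did not pass the camera test with telmisartan. Lipogenesis had 9 higher and 10 lower (camera adjusted p = 0.857), lipolysis 3 and 3 (0.738) and glycolysis 7 and 4 (0.254). Secreted factors had 3 and 7 (0.0877, or 0.0197 with no dye term) and renin-angiotensin 0 and 3 (0.738). Brown fat had 4 and 3 (0.747), oxidative stress 9 and 11 (0.738), heat shock 4 and 4 (0.857), circadian 1 and 3 (0.826) and glucocorticoid 5 and 6 (0.857). Several of these passed by fry, which compares with no other genes, among them brown fat (fry adjusted p = 3.12e-08) and glycolysis (1.41e-07). Among other cell types the counts were macrophage 1 and 1 (0.86), endothelial 2 and 2 (0.86), muscle 3 and 4 (0.857), hepatocyte 1 and 0 (0.826) and blood 0 and 1 (0.712). Brown fat genes had a median of -0.05 and a mean of 0.24, and blood cell genes also differed in sign between median and mean.

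Irbesartan raised Elovl3 as well (2.52 ± 0.05, adjusted p = 4.71e-10), with Arxes1 (1.33 ± 0.10), Cycs (1.26 ± 0.04) and Olr1 (1.23 ± 0.12). Lowered genes included Camp (-1.45 ± 0.12, adjusted p = 3.44e-06), Sertad4 (-1.34 ± 0.03) and Adcyap1r1 (-1.26 ± 0.16). Genes of respiration, the citrate cycle, fatty acid oxidation, cholesterol synthesis, glycolysis and lipolysis were higher, and those of the matrix, inflammation and the interferon response were lower. Of 17217 features 5393 passed, 2487 higher and 2906 lower, with 302 at 1.5-fold or more and 6661 at an unadjusted p under 0.05. With no dye term 3439 passed, and in a separate fit of the irbesartan arrays 6397 of 19344.

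Irbesartan also raised 4931406C07Rik (1.26), Krt23 (1.25), the aldehyde dehydrogenase gene Aldh1a7 (1.14), Ms4a4d (1.10), Ero1a (1.05) and Idh3a (0.98). It also lowered Cyp2f2 (-1.24), Numa1 (-1.20, and -0.25 at its other spot), Aff3 (-1.20), Dcn (-1.17), Abi3bp (-1.08), Hp (-1.08) and Tgfbi (-1.02). Oxidative phosphorylation genes rose in 60 of 69 cases and fell in 2 (median 0.24, camera adjusted p = 3.98e-22), with 63 and 2 adjusted over the list alone. Uqcrfs1 (0.55) and Atp5o (0.47) followed Cycs. Citrate cycle genes rose in 17 of 22 cases and fell in 1 (median 0.31, camera adjusted p = 7.04e-10), with 18 and 1 adjusted over the list alone, and Cs was at 0.69. Fatty acid oxidation genes rose in 17 of 24 cases and fell in 0, adjusted over the list alone too, with Slc25a20 at 0.79 and Hadhb at 0.66 (median 0.20, camera adjusted p = 4.2e-09). Cholesterol synthesis genes rose in 18 of 20 cases and fell in 1, adjusted over the list alone too, with Idi1 at 0.91 and Lss at 0.79 (median 0.47, camera adjusted p = 1.27e-12). Glycolysis genes rose in 11 of 18 cases and fell in 1, adjusted over the list alone too, with Pfkfb3 at 0.88 and Slc16a1 at 0.57 (median 0.20, camera adjusted p = 2.33e-05). Lipolysis genes rose in 6 of 9 cases and fell in 0, adjusted over the list alone too, among them the lipase genes Pnpla2 (0.42) and Mgll (0.42) and the lipase activator gene Abhd5 (0.52; median 0.14, camera adjusted p = 0.000869). Lipogenesis genes rose in 11 of 20 cases and fell in 5, or 12 and 5 adjusted over the list alone, with Mogat1 at 0.78 and Gpd1 at 0.72 (median 0.10, camera adjusted p = 0.0148, adjusted p = 0.2 with an estimated correlation). Brown fat genes rose in 4 of 11 cases and fell in 1, adjusted over the list alone too, with Ppargc1a at 0.28 (median 0.13, camera adjusted p = 0.0041). ER stress genes rose in 14 of 24 cases and fell in 3, or 16 and 3 adjusted over the list alone, with Asns at 0.65 and Atf4 at 0.50 (median 0.18, camera adjusted p = 1.99e-05).

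Matrix genes fell in 28 of 43 cases and rose in 1 with irbesartan (median -0.23, camera adjusted p = 1.59e-09), with 29 and 3 adjusted over the list alone, among them Col1a2 (-0.83) and Fn1 (-0.82). Fibroblast markers fell in 11 of 15 cases and rose in 0, adjusted over the list alone too, with Pdgfra at -0.86 and Vim at -0.82 (median -0.40, camera adjusted p = 4.2e-09). Actin and contractile genes fell in 14 of 23 cases and rose in 2, adjusted over the list alone too, with Myl9 at -0.70 (median -0.22, camera adjusted p = 8.84e-05, adjusted p = 0.0641 with an estimated correlation). Inflammation genes fell in 14 of 28 cases and rose in 1, adjusted over the list alone too, with the chemokine gene Cxcl5 at -0.57 and the adhesion molecule gene Vcam1 at -0.57 (median -0.20, camera adjusted p = 4.5e-06). Interferon response genes fell in 12 of 24 cases and rose in 2, or 13 and 2 adjusted over the list alone, with Ifit3 at -0.80 and Stat2 at -0.46 (median -0.17, camera adjusted p = 0.00481). Ribosomal protein genes fell in 39 of 63 cases and rose in 2, or 43 and 2 adjusted over the list alone, with Rps27 at -0.33 (median -0.15, camera adjusted p = 1.27e-08, adjusted p = 0.059 with an estimated correlation). PPAR-gamma targets rose in 14 of 25 cases and fell in 6, adjusted over the list alone too (median 0.09, camera adjusted p = 0.00113), with Aqp7 (0.88), Pdk4 (0.86 ± 0.04), Angptl4 (0.66 ± 0.03) and Cd36 (0.63 ± 0.03) among the rises.

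Pparg fell by 0.54 ± 0.03 with irbesartan and Agt by 0.11 ± 0.02 (adjusted p = 0.00291, or 0.087 with no dye term). Retn was at 0.09 ± 0.03 (adjusted p = 0.0182), which did not pass without irbesartan arrays 1 (0.0717) or 4 (0.118), with no dye term (0.189) or in its own fit (0.0696). Slc2a4 (0.03, adjusted p = 0.418), Agtr1a (0.01, 0.924) and Lep (0.03, 0.461) did not pass. Fabp4 and Lpl shared a ratio with other spots on irbesartan arrays 1 and 3, and Adipoq on array 3. Fitted over the 4 arrays, Fabp4 was at -0.09 ± 0.14 (adjusted p = 0.724), Adipoq at -0.37 ± 0.08 (0.0027) and Lpl at -0.42 ± 0.14 (0.0359). The SE of Lpl is that shared by the drugs. Lpl read -0.34, -0.41, -0.40 and -0.52 on irbesartan arrays 1 to 4, against -0.44, 0.35, -0.27 and -0.73 on those of telmisartan. Lpl lost its call without any of the irbesartan arrays 1 to 4 (0.0897, 0.086, 0.106 and 0.123) and without pioglitazone arrays 2 (0.0506) or 3 (0.0518) or telmisartan array 3 (0.0517). Cell cycle genes gave 11 higher and 6 lower of 34, or 13 and 6 adjusted over the list alone (median 0.11, camera adjusted p = 0.056). The test passed without pioglitazone arrays 1 (0.0445) or 3 (0.0358), telmisartan arrays 2 (0.0199) or 4 (0.0382) or irbesartan arrays 1 (0.0427) or 3 (0.0456). It also passed with no dye term (0.0248), the block (0.0435), pairs averaged (0.0477) and scaled arrays (0.0332). No shift passed for thiazolidinedione-repressed genes (1 higher and 3 lower, camera adjusted p = 0.161), insulin signalling (2 and 7, 0.199), secreted factors (5 and 6, 0.809), adipogenic regulators (5 and 8, 0.492), renin-angiotensin (2 and 4, 0.582), oxidative stress (11 and 9, 0.619), heat shock (6 and 2, 0.132), circadian (1 and 5, 0.172) or glucocorticoid genes (4 and 5, 0.809). All of these lists but oxidative stress passed by fry, which compares with no other genes, among them thiazolidinedione-repressed genes (fry adjusted p = 1.98e-06). For other cell types the counts were macrophage 0 and 1 (0.927), endothelial 1 and 3 (0.951), muscle 2 and 2 (0.927), hepatocyte 2 and 0 (0.67) and blood 0 and 1 (0.951). Median, mean and test did not all have 1 sign for oxidative stress, macrophage, endothelial and blood cell genes.

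**Figure D2:**
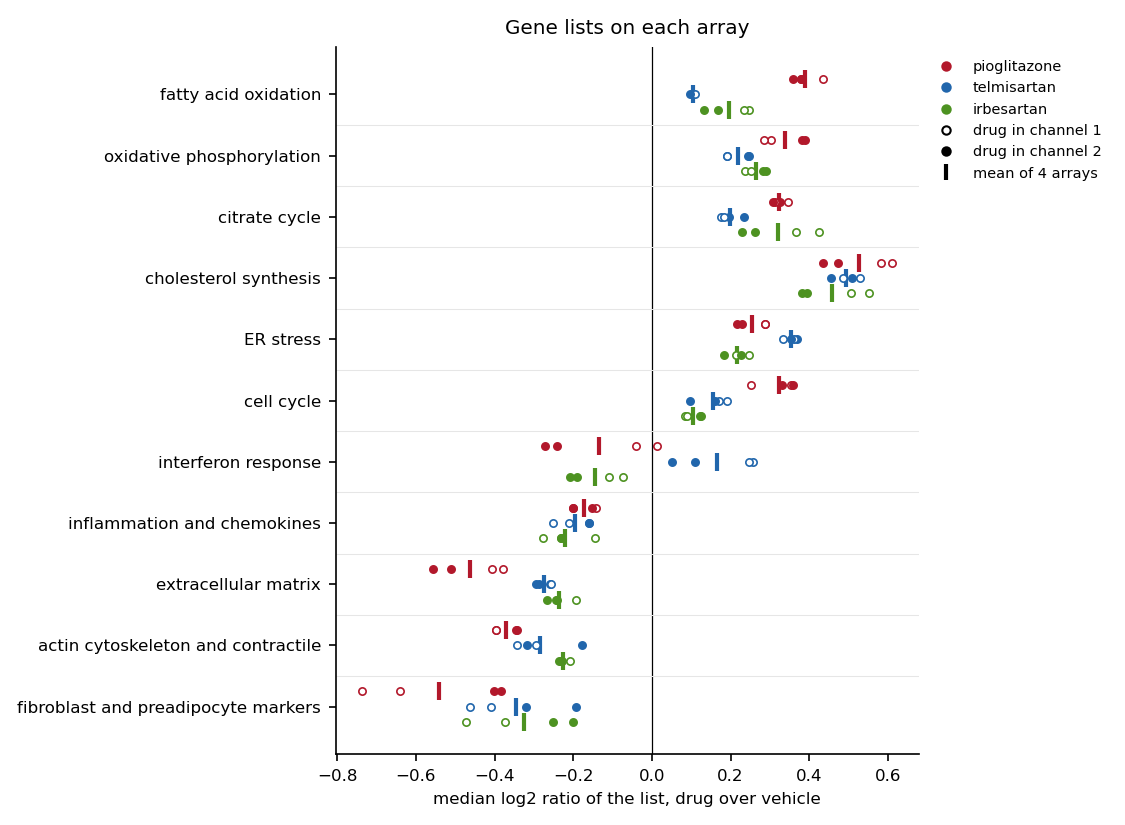
Median log2 ratio of drug over vehicle of 11 fixed gene lists on each of the 12 arrays, with open points for the drug in channel 1, filled points for channel 2 and a bar for the mean of 4 arrays. Oxidative phosphorylation and cholesterol synthesis genes lie above 0 and matrix genes and fibroblast markers below 0 on every array, and interferon response genes lie above 0 on the 4 telmisartan arrays and below 0 on the 4 irbesartan arrays.

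The drugs moved many genes the same way. Elovl3 and Krt23 rose and Camp, Adcyap1r1, Cyp2f2, Dcn and Pparg fell with all 3 drugs, and 1726 features were higher and 1997 lower with all 3, against 117 and 161.2 if the calls were independent. Of these, 77 were higher and 118 lower by at least 1.5-fold in each. Across the 17217 features, which are not independent replicates, the fitted ratios of pioglitazone and telmisartan correlated with Pearson's r = 0.814 and Spearman's rho = 0.756. The values were 0.794 and 0.715 for pioglitazone and irbesartan and 0.747 and 0.652 for telmisartan and irbesartan. With arrays turned in fixed patterns (16 combinations for each pair), the largest absolute r was 0.085, 0.031 and 0.067 for these 3 pairs. These patterns cancel a drug effect, a shared vehicle and the channel order alike, so a low r was given by their construction. Pioglitazone had the widest ratios, with an SD of 0.30 against 0.22 for telmisartan and 0.19 for irbesartan. Opposite calls were made for 146, 120 and 109 features in these pairs, and 0 of them reached 1.5-fold with both drugs. A shared vehicle RNA, on which the labels are silent, would by itself make the ratios of different drugs correlate.

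**Figure D3:**
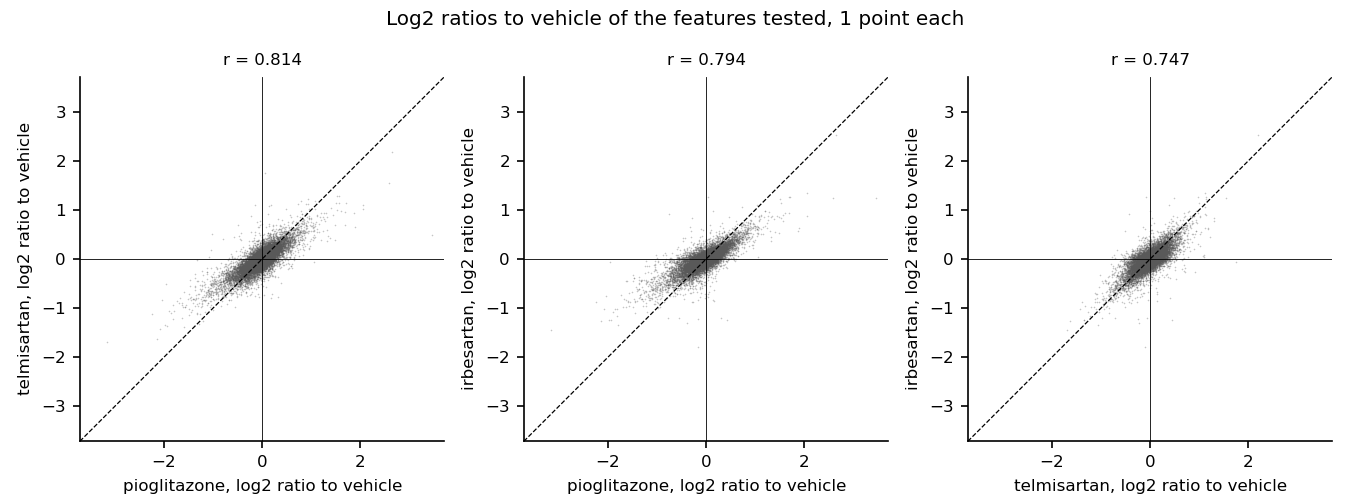
Fitted log2 ratio of drug over vehicle of each of the 17217 features, plotted for each pair of drugs, with a dashed line where the ratios are equal. The correlations are 0.814, 0.794 and 0.747, and pioglitazone's ratios spread more widely than those of telmisartan or irbesartan.

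Pioglitazone and telmisartan differed most in Olr1, which was higher with pioglitazone by 2.96 ± 0.16 (95% interval 2.60 to 3.33, adjusted p = 2.57e-06). They also differed in the interferon-induced genes Gbp3 (-1.52 ± 0.04, interval -1.62 to -1.42, adjusted p = 4.81e-08) and Ifit3 (-1.21 ± 0.08, interval -1.39 to -1.03), which were lower with it. Fatty acid oxidation and respiration genes were higher, and matrix genes lower, with pioglitazone than with telmisartan. Of 17217 features 2526 differed, 1045 higher and 1481 lower with pioglitazone, 140 of them at least 1.5-fold. With no dye term 838 differed. The doses are not in the labels, so they may not match. Fosl1 (1.10), Krt23 (1.04), Pdk4 (1.04 ± 0.06) and Cbr3 (1.00) were higher with pioglitazone, and Camp (-1.47), the aldo-keto reductase gene Akr1c14 (-1.31) and Ogn (-1.21) were lower. Fatty acid oxidation genes were higher in 17 of 24 cases and lower in 0, or 19 and 0 adjusted over the list alone (median 0.22, camera adjusted p = 5.75e-14), with Cpt1a, which admits fatty acids to mitochondria, at 0.51 ± 0.04. Oxidative phosphorylation genes were higher in 34 of 69 cases and lower in 1, or 41 and 3 adjusted over the list alone, with Cycs at 0.71 (median 0.14, camera adjusted p = 3.9e-14). PPAR-gamma targets were higher in 13 of 25 cases and lower in 3, adjusted over the list alone too, with Fabp5 at 0.79 (median 0.16, camera adjusted p = 2.49e-07). This list set the direction of the ratios on the pioglitazone arrays, so its direction here is not independent of that choice. Brown fat genes were higher in 6 of 11 cases, adjusted over the list alone too, with Ppargc1a at 0.55 and Cidea at 0.48 (median 0.16, camera adjusted p = 0.000108). Cell cycle genes were higher in 11 of 34 cases, or 14 adjusted over the list alone (median 0.14, camera adjusted p = 9.91e-07). Oxidative stress genes were higher in 13 of 29, with 3 lower, or 13 and 4 adjusted over the list alone and Gclc at 0.46 (median 0.09, camera adjusted p = 0.00235).

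Matrix genes were lower with pioglitazone than with telmisartan in 24 of 43 cases and higher in 2, or 29 and 2 adjusted over the list alone, with Lox at -1.04 and Lum at -0.89 (median -0.23, camera adjusted p = 3.1e-13). Interferon response genes were lower in 12 of 24 cases and higher in 1, or 14 and 2 adjusted over the list alone (median -0.35, camera adjusted p = 2.49e-07). Fibroblast markers were lower in 8 of 15 cases, or 8 with 3 higher adjusted over the list alone, with S100a4 at -0.66 and Pdgfra at -0.59 (median -0.19, camera adjusted p = 5.95e-05). Calls lost with an estimated correlation were those for the citrate cycle (9 of 22 higher, adjusted p = 8.11e-05, adjusted p = 0.0631 with an estimated correlation), heat shock (4 of 14 higher, 0.0204 and 0.12), ribosomal proteins (13 of 63 lower, 0.00115 and 0.295) and the circadian clock (4 of 17 lower, 0.0375 and 0.12). The circadian call also ended without pioglitazone array 3 (0.0602), telmisartan array 2 (0.0569) or irbesartan array 2 (0.0508), with pairs averaged (0.109) and with a dye term per drug (0.0866). The heat shock call ended with no dye term (0.0561). Agt (-0.42, interval -0.49 to -0.34) and Pparg (-0.47, interval -0.55 to -0.39) were lower with pioglitazone. Cholesterol synthesis genes did not pass the camera test as a group (camera adjusted p = 0.303), and 5 were higher and 5 lower.

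Against irbesartan, pioglitazone again had higher Olr1 (2.22 ± 0.16, 95% interval 1.85 to 2.58, adjusted p = 1.65e-05), Krt23 (1.33 ± 0.12) and Pdk4 (1.18 ± 0.06) and lower Camp (-1.71 ± 0.17, interval -2.07 to -1.34) and Ogn (-1.29 ± 0.04). Cell cycle genes were higher and matrix genes lower with pioglitazone, and respiration and fatty acid oxidation genes were higher, though not past the threshold with scaled arrays. Of 17217 features 3113 differed, 1312 higher and 1801 lower, 196 of them at least 1.5-fold. There were 1044 with no dye term and 1763 with arrays scaled to 1 median absolute value. Fosl1 (0.96) and Zbtb7a (0.97) were also higher, and Phkg1 (-1.35) and Mrc2 (-1.18) lower. Lars2, a spot that shared its ratio with Fabp4 on 6 arrays (1 and 3 of each drug), was at -1.20 ± 0.21 (adjusted p = 0.0028, or 0.0558 with no dye term). Cell cycle genes were higher in 19 of 34 cases and lower in 0, or 22 and 0 adjusted over the list alone, with Cks2 at 0.65 and Mki67 at 0.44 (median 0.24, camera adjusted p = 1.98e-09). Matrix genes were lower in 26 of 43 cases, or 32 adjusted over the list alone, with Lox at -1.09, Lum at -1.01 and Fn1 at -0.84 (median -0.22, camera adjusted p = 1.7e-16). Fatty acid oxidation genes were higher in 12 of 24 cases and lower in 1, or 15 and 1 adjusted over the list alone, with Cpt1a at 0.53 (median 0.14, camera adjusted p = 2.72e-05, or median 0.08 and 0.0528 with scaled arrays). Oxidative phosphorylation genes were higher in 31 of 69 cases and lower in 3, or 36 and 4 adjusted over the list alone, with Uqcrc2 at 0.34 (median 0.11, camera adjusted p = 5.28e-08, or median 0.04 and 0.0548 with scaled arrays). PPAR-gamma targets were higher in 10 of 25 cases and lower in 3, adjusted over the list alone too, with Hilpda at 0.88 (median 0.10, camera adjusted p = 0.00285, or median 0.05 and 0.0893 with scaled arrays). Here too the direction of this list is not independent of the reading it served to choose.

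Of the lipogenesis list, Thrsp (-1.16 ± 0.04), Dgat2 (-0.75 ± 0.06) and the fatty acid synthase gene Fasn (-0.49 ± 0.04) were lower with pioglitazone than with irbesartan. As lists, lipogenesis (8 lower and 4 higher of 20, camera adjusted p = 0.0419, adjusted p = 0.259 with an estimated correlation), lipolysis (3 and 0 of 9, 0.0489 and 0.141), secreted factors (7 and 1 of 15, 0.0222 and 0.0863), and fibroblast markers (8 and 1 of 15, 0.00133 and 0.0548) lost their calls with an estimated correlation. The actin genes did too (9 and 0 of 23, 0.0105 and 0.246). The lipogenesis call also ended without pioglitazone arrays 2 (0.0618) or 4 (0.0523) or telmisartan array 4 (0.0502). That for lipolysis ended without pioglitazone arrays 2 (0.065) or 4 (0.0586), telmisartan arrays 2 (0.0577) or 4 (0.0577) or irbesartan arrays 2 (0.0853) or 4 (0.0655). The secreted factor call ended with pairs averaged (0.0555), the lipolysis call with the block (0.059) and pairs averaged (0.056), and those for actin (0.207) and fibroblast genes (0.38) with scaled arrays. Retn (-0.71 ± 0.04) and Pparg (-0.55 ± 0.04) were lower with pioglitazone. Interferon response genes did not pass the camera test as a group, with 5 higher and 3 lower of 24 (camera adjusted p = 0.866).

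Telmisartan and irbesartan differed most in interferon-induced genes, which were higher with telmisartan: Ifit3 by 1.21 ± 0.08 (95% interval 1.03 to 1.39, adjusted p = 4.13e-05), the ubiquitin-like modifier gene Isg15 by 1.18 ± 0.07 (interval 1.01 to 1.34, adjusted p = 3.84e-05), Rtp4 by 0.97 ± 0.06, Trim30a by 0.93 ± 0.08 and Ifit1 by 0.94 ± 0.18 (telmisartan n = 3, adjusted p = 0.011). Several genes of lipogenesis and lipolysis were lower with telmisartan, among them Thrsp (-0.69 ± 0.04, interval -0.79 to -0.59), Mgll (-0.53 ± 0.04) and the acetyl-CoA carboxylase gene Acaca (-0.48 ± 0.07, and -0.41 at its other spot). The ER stress genes Ddit3 (0.47 ± 0.07) and Hspa5 (0.43 ± 0.04) were higher with telmisartan. Of 17217 features 1615 differed, 854 higher and 761 lower with telmisartan, and 23 of them at least 1.5-fold. These compounds are both biphenyl receptor blockers, and their doses, which the labels do not give, may differ. The count was 266 with no dye term, 866 in a fit of the 8 arrays alone and 2564 with a dye term per drug. It was 1056 without telmisartan array 1, 974 without telmisartan array 3, 1019 without irbesartan array 1 and 1015 without irbesartan array 4.

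Interferon response genes were higher with telmisartan than with irbesartan in 12 of 24 cases and lower in 0, adjusted over the list alone too, with Mx2 at 0.88 ± 0.07 (median 0.24, camera adjusted p = 1.86e-07). ER stress genes were higher in 10 of 24 cases, or 13 with 2 lower adjusted over the list alone (median 0.13, camera adjusted p = 0.000234). Lower as groups with telmisartan were lipogenesis (6 of 20, or 13 adjusted over the list alone; median -0.15, camera adjusted p = 1.86e-07), lipolysis (4 of 9, or 5, median -0.16, 0.000443) and fatty acid oxidation (6 of 24, or 8, median -0.08, 0.000124). So were glycolysis (3 of 18 with Slc16a1 higher by 0.37, or 7 and 1; median -0.09, 0.00372) and secreted factors (4 of 15, or 6; median -0.07, 0.000972). Retn (-0.43 ± 0.04), Ppargc1a (-0.40 ± 0.05) and Cidea (-0.34 ± 0.04) were among the lower genes. Calls with a median above 0 that were lost with an estimated correlation were those for ribosomal proteins (median 0.083, camera adjusted p = 0.000304, adjusted p = 0.196 with an estimated correlation) and cell cycle (0.07, 0.0155 and 0.167). Lost calls with a median below 0 were those for citrate cycle (-0.076, 0.00106 and 0.11) and thiazolidinedione-repressed genes (-0.093, 0.00591 and 0.0502). The same was true of brown fat (-0.14, 0.0155 and 0.0704), adipogenic regulators (-0.097, 0.0197 and 0.21), actin (-0.085, 0.0262 and 0.263), matrix (-0.052, 0.038 and 0.302) and PPAR-gamma targets (-0.061, 0.0429 and 0.106). Leaving out 1 array ended some of these as well, with brown fat lost without telmisartan array 2 (0.0556) and actin without telmisartan array 3 (0.0539). The matrix call ended without telmisartan arrays 3 (0.061) or 4 (0.0985) or irbesartan arrays 2 (0.0835) or 4 (0.0556), and that of PPAR-gamma targets without telmisartan arrays 3 (0.0695) or 4 (0.132) or irbesartan arrays 3 (0.055) or 4 (0.0818). The matrix median was -0.05, and 0.01 with scaled arrays. Scaled arrays also ended the calls for thiazolidinedione-repressed genes (0.0665), adipogenic regulators (0.0946) and actin (0.263). Lists without a call that passed with scaled arrays were fibroblast markers (median 0.01, or 0.13 and 0.00272 when scaled), heat shock (-0.06, or -0.08 and 0.047) and cholesterol synthesis (0.04, or -0.07 and 0.047). Oxidative phosphorylation genes had a median of -0.04 (camera adjusted p = 0.0521), and of -0.08 with scaled arrays (7.69e-06). They also passed with centred arrays (0.0462), with a dye term per drug (0.0497) and without pioglitazone array 3 (0.0412), telmisartan arrays 1 (0.0368) or 3 (0.0484) or irbesartan arrays 1 (0.0204) or 3 (0.0464). Insulin signalling genes (median -0.06, camera adjusted p = 0.059) passed without telmisartan arrays 1 (0.0368) or 4 (0.0468). Of the named genes, Tlcd3b (-0.63 ± 0.05) passed at each setting tried, whereas Olr1 (-0.75 ± 0.16, adjusted p = 0.0179), Ms4a4d (-0.72 ± 0.17, 0.0271) and Psap (-0.63 ± 0.15, 0.0251) each lost their call when 1 array was left out. Olr1 did so without telmisartan array 3 (0.0537) or irbesartan arrays 2 (0.0519) or 3 (0.0507). Ms4a4d did so without telmisartan arrays 1 (0.0821) or 3 (0.0842) or irbesartan arrays 1 (0.0741) or 4 (0.0738), and Psap did so without telmisartan arrays 1 (0.0771) or 3 (0.0754) or irbesartan arrays 1 (0.0769) or 3 (0.0693). In a fit of the 8 arrays alone their adjusted p-values were 0.0525, 0.0616 and 0.0972, and with no dye term those of Ms4a4d and Psap were 0.0904 and 0.343. Psap also did not pass with the block (0.0629) or scaled arrays (0.0734). Several genes did not differ past the threshold: Pparg (-0.08, interval -0.16 to 0.00), Cd36 (0.04, interval -0.06 to 0.15), Agt (-0.07, interval -0.14 to 0.00) and Agtr1a (0.10, interval -0.05 to 0.24).

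**Figure D4:**
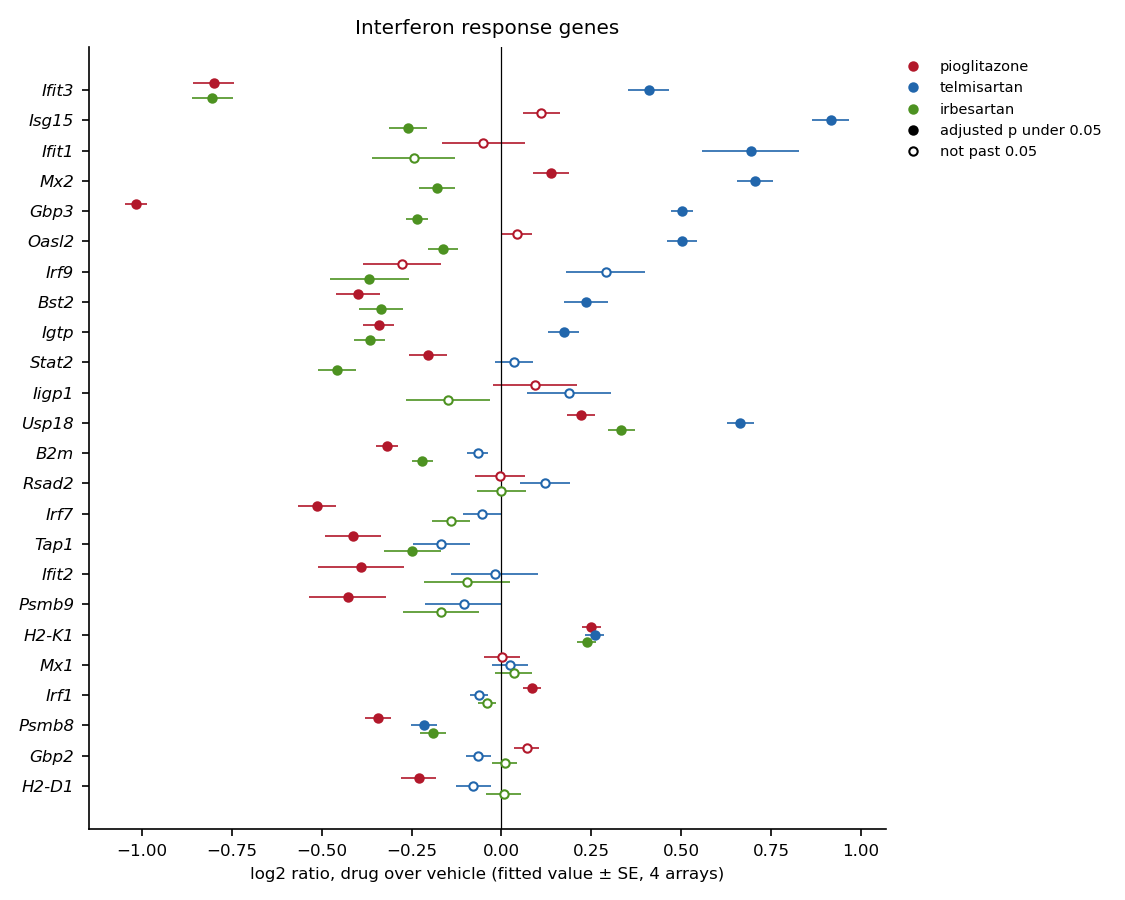
Fitted log2 ratio of drug over vehicle ± SE of 24 interferon response genes with each drug, ordered by the difference between telmisartan and irbesartan, with filled points where the adjusted p is under 0.05. Ifit3 and Isg15 stand at the top of the order, with differences of 1.21 and 1.18.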

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

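In this part the tests on spots that share a ratio and on macrophage and blood cell markers were chosen after the result was seen, and the other tests before. Telmisartan and irbesartan moved interferon response genes apart, with a median difference of 0.242 (12 of 24 genes higher with telmisartan and 0 lower), and pioglitazone and telmisartan differed in them by -0.346. Leaving out any 1 of the 8 arrays argues against 1 array as the source, since the median difference between telmisartan and irbesartan stayed between 0.189 and 0.304 and the largest camera adjusted p was 8.09e-07. The channel order is argued against by differences of 0.296 with the drug in channel 1 and 0.22 with it in channel 2. Macrophages or blood cells in a culture would raise their own abundant genes. The macrophage list had a median difference of 0.005 (highest for Adgre1, 0.087) and the blood list one of -0.02 (highest for Cd8a, 0.182). Whether these markers stood above background is not known, so their flat values decide little. A difference between culture pools rather than between compounds cannot be told apart, because the labels do not say how many pools each drug had, and a pool would give the same 0.242; a compound effect on interferon signalling may be the reason, as a hypothesis.

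Features called in opposite directions were also picked out as differences between drugs. There were 146 between pioglitazone and telmisartan, 120 between pioglitazone and irbesartan and 109 between telmisartan and irbesartan, against 1759.6, 1339.3 and 1104.4 if the calls were independent.

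Single arrays far from the other 3 of their drug were sought in 193 groups of 4 values, and 5 passed Dixon's 95% criterion, where chance gives about 1 in 20 groups, or 9.7. Each was on a different array. The median of PPAR-gamma targets was 0.0678 on irbesartan array 2 against 0.144 to 0.158 on the others. That of lipogenesis genes was -0.137 on telmisartan array 4 against -0.0167 to -0.0022, and that of heat shock genes 0.1377 on telmisartan array 2 against -0.0444 to -0.0137. Tgfbi was at -1.933 on pioglitazone array 4 against -1.796 to -1.779, and Adipoq at -0.639 on pioglitazone array 1 against -1.076 to -1.037. The -1.037, on array 3, is a ratio that Adipoq shared with Fabp4.

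Several spots shared 1 ratio with Fabp4 on arrays with the drug in channel 1. On those of pioglitazone and irbesartan 5 spots (Fabp4, Lars2, Lpl, Pigt and a probe with no gene) had the same ratio on at least 3 of 4 arrays, and 13 had it on at least 2. Chance would give 0.00033 and 0.403 if the arrays were independent. The arrays of each drug in this order correlated (0.8787 for pioglitazone and 0.6981 for irbesartan), so these chance values are too low. Some also shared a ratio on telmisartan arrays 1 (Fabp4, Lars2 and Lpl) and 3 (Fabp4, Lars2 and Pigt), and others on irbesartan arrays 2 and 4 (Lars2, Pigt and Aldoa on both), but on pioglitazone arrays 2 and 4 the 5 spots spread over at least 2.505 on the log2 scale, which argues against saturation of both channels for all 5 there. A scanner signal saturated in both channels is a candidate explanation for the arrays where they share a ratio, but the count of 5 is the observation that prompted it and gives it no support. It stays open, since intensities were not analysed here, and no biological explanation was tested.

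Cell cycle genes kept a median of at least 0.27 with pioglitazone when any 1 of its 4 arrays was left out.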

How the results depend on the processing

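The own dye term per drug, the minimum of 1.5-fold, scaled arrays for the list tests and the check of direction over all spots were chosen after the data were seen. Feature counts stayed within 1.5 times their value with the block, averaged pairs, centred arrays, complete features, no filter, robust variances and array weights. Leaving out 1 array gave 7313 to 9425 for pioglitazone, 6003 to 7558 for telmisartan, 4391 to 6010 for irbesartan, 1758 to 2572 for pioglitazone against telmisartan and 2185 to 3787 for pioglitazone against irbesartan. For telmisartan against irbesartan the range was 974 (without telmisartan array 3) to 2084 (without telmisartan array 2). Correlations ranged over all alternatives from 0.646 to 0.853. Of the features called, 0 were called with the opposite sign under the alternatives that test the same features; with spots of a gene averaged they were not compared.

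With no dye term irbesartan gave 3439 features, pioglitazone against telmisartan 838, pioglitazone against irbesartan 1044 and telmisartan against irbesartan 266. Scaled arrays gave 1763 for pioglitazone against irbesartan, where 6 lists passed. For telmisartan against irbesartan a fit of the 8 arrays gave 866 and a dye term per drug 2564. For these the cause was not tested. A minimum of 1.5-fold left 981, 414, 302, 140, 196 and 23, by its construction. An estimated correlation left 8 lists for pioglitazone, 7 for telmisartan, 5 for pioglitazone against irbesartan and 7 for telmisartan against irbesartan. With fry, which compares with no other genes, 26, 23, 25, 22 and 22 passed for pioglitazone, telmisartan, irbesartan and pioglitazone against each blocker. Leaving out 1 array gave 13 to 14, 14 to 16, 16 to 17, 12 to 14, 8 to 10 and 14 to 18 lists. Hp reversed between telmisartan and irbesartan with scaled arrays (0.043, adjusted p = 0.747; the cause was not tested), and the correlation of opposite channel orders was 0.7514 over all spots, because control-like spots are included.

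Named genes kept their direction and side of the threshold in 18366 cases, lost a call in 747, gained one in 44 and reversed in 1. For lists these were 3732, 79 and 93, and 2 without a call changed direction and passed: cholesterol synthesis between telmisartan and irbesartan with scaled arrays (-0.07, adjusted p = 0.047) and blood cell genes with pioglitazone by fry (0.00742). Flooring of linear values was not run, since the values are logarithms. Signal over background was not analysed here, so faint spots could not be told from bright ones.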

Other observations

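The tests in this part on the correlation of the drugs, on gene families and on splits balanced for channel order were chosen after the results were seen, and the full set of splits of the arrays before. Among 137 families of genes that share a symbol stem, those of mitochondrial ribosomes and protein import rose. Mrpl genes rose in 32 of 43 cases and fell in 4 with pioglitazone (median 0.22, camera adjusted p = 1.03e-06, or 0.0376 with an estimated correlation), in 26 and 1 with telmisartan (0.12, 0.000154, or 0.141) and in 33 and 2 with irbesartan (0.16, 7.02e-09, or 0.0249). Mrps genes rose in 18 of 28 cases with pioglitazone (0.000287, or 0.0376), 13 with telmisartan (0.0168, or 0.141) and 16 with irbesartan (3.01e-05, or 0.0249). Timm genes, for import into mitochondria, rose in 10 of 14 cases with pioglitazone (median 0.48, 0.00121, or 0.0756), 9 with telmisartan (0.0146, or 0.141) and 10 with irbesartan (5.29e-05, or 0.0334). Collagen genes fell in 19 of 32 cases and rose in 4 with pioglitazone (median -0.19, 0.000192, or 0.0376), in 19 and 3 with telmisartan (-0.17, 8.93e-05, or 0.0825) and in 14 and 1 with irbesartan (-0.04, 0.00254, or 0.0737). Histone deacetylase genes fell in 8 of 10 cases with pioglitazone (0.0113, or 0.429), 6 with telmisartan (0.0152, or 0.514) and 6 with irbesartan (0.0438, or 0.597). The families past the test numbered 11, 9 and 11 for the drugs and 11, 5 and 0 for the differences, and 4, 0, 4, 0, 0 and 0 with an estimated correlation.

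The correlation of the drugs' ratios was weighed against a vehicle RNA shared by all arrays. Such a vehicle would add the same covariance to each pair if the ratios of all drugs have 1 scale, which was not tested. The covariances were 0.0537, 0.0452 and 0.0321. Their largest difference was 0.0216, against at most 0.0046 between arrays 1 and 2 and arrays 3 and 4. On an equal scale this argues against a shared vehicle as the whole cause. With unequal scales it decides nothing, and pioglitazone's ratios spread most widely. Even on an equal scale a shared part of up to 0.0321 stays open, because the labels do not say whether the vehicle was shared. The blockers may, as a hypothesis, carry a smaller copy of the pioglitazone pattern: scaled to each blocker it gives 88.3% of their covariance (0.0283 of 0.0321). The share was 95.5% or 82.5% when each covariance was taken between arrays 1 and 2 on 1 side and arrays 3 and 4 on the other. Each of these shares could also hold a shared vehicle.

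Olfactory receptor genes, 534 in number, had a median of 0.08 with pioglitazone, with 167 higher and 13 lower and 0 at 1.5-fold (camera adjusted p = 0.000393, and not past the threshold with an estimated correlation). The medians were 0.05 with telmisartan and 0.03 with irbesartan. The medians followed the channel order with each drug. With pioglitazone they were 0.0067 and 0.0292 with the drug in channel 1 and 0.132 and 0.126 with it in channel 2. In the same order they were 0.0266 and 0.0159 against 0.0476 and 0.0942 with telmisartan. With irbesartan they were -0.0176 and -0.0106 against 0.0652 and 0.0593. Of these genes 33.7%, 19.9% and 5.1% passed with pioglitazone, telmisartan and irbesartan, beside 49.9%, 41% and 31.3% of all features. The cause was not tested. Features called with an absolute ratio under 0.2 numbered 3296, 2927 and 2321 for the drugs.

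Other splits of the arrays were counted for each result. For a drug against vehicle there are 8 patterns of turned arrays, too few for a share under 0.05. The real feature counts and the highest others were 8587 and 0 for pioglitazone (1 of 8 as large), 7067 and 475 for telmisartan (1 of 8) and 5393 and 2 for irbesartan (1 of 8). For lists they were 13 and 14 (2 of 8), 15 and 12 (1 of 8) and 16 and 16 (2 of 8). For differences between drugs there are 35 splits, and 1 of 35 was as large in each case, a share under 0.05. The real and highest other feature counts were 2526 and 39 for pioglitazone against telmisartan, 3113 and 4 for pioglitazone against irbesartan and 1615 and 18 for telmisartan against irbesartan, and the list counts 13 and 11, 10 and 8, and 16 and 11. Of the 35, 17 mix the channel orders unevenly, and the other 18 are too few for a share under 0.05. Arrays of opposite channel order are not interchangeable, so the splits do not exclude chance, and spread between RNA pools is not covered. Splits that mix the drugs also put the difference between them into the spread, which lowers their counts. Among the 18 balanced splits the highest other feature counts were 0, 0 and 18, and the highest other list counts 11, 8 and 7, so some list counts lie close to the real ones.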
